A study of Danio rerio with 11 samples.

How the data were processed

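Total RNA of 11 zebrafish livers (6 healthy, 5 with a DMBA-induced tumor) was measured on 2-colour Agilent arrays. Per the labels' protocols, RNA integrity numbers averaged 9 with a minimum of 8, amino-allyl aRNA was made in a single amplification round from 1 µg of total RNA, and 6 µg of it was coupled to dye. Each liver was labelled with Cy5 and hybridised with a Cy3-labelled common reference, a mixture of the 11 RNAs per the labels. Whether the values behave as ratios to an equal mixture was checked after the data were examined, on the mean of the linear ratios over the 11 arrays, and they did not: the reference read closer to healthy liver than an equal mixture would on probes that differed between the groups. By median centring and by the processed signals, 1008 and 995 of the 1008 probes at least 2-fold higher had a tumor mean above the limit of 1.14 of an equal mixture. The tumor share of the reference that fitted best was 0%, the lowest share tried, for higher and lower probes, but 23% for lower probes by median centring. By loess the median group means of the lower probes were both below 0 (-0.40 in healthy livers, -2.01 in tumors). A share at the edge of the range tried is therefore not a fitted composition. No dye swap was made, so a dye effect of a probe cancels only between the groups. Groups and replicate numbers were taken from the sample titles.

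Spot mean and local background median intensity in both channels, in linear units, were written by Agilent Feature Extraction 9.5.3.1, per the file headers, together with flags for outlier spots, saturation and signal well above background. Processed intensity signals in the same files were background-subtracted and dye-normalized within each array by that software, per the file headers. The authors' deposited value table holds the log10 ratio of Cy5 over Cy3. Each of its columns equals the log10 ratio in that array's scanner file (largest difference 0) and has a median of 0, so its scale, centring and direction are known. The genome build behind the probe sequences was not used.

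Each array carried 44787 spots, 1417 of them controls. The other 43370 spots have a name each, and their gene columns repeat the probe name (0 differ) with no description or genome position (0 probes each). The reference tables of gene names hold no probe identifiers. Genes were therefore not named, the 2 rules on named genes and cell type markers could not be applied to genes, and the tests of gene lists were not run. In their place the text names at most 2 probes that rose and 2 that fell, by the same rule, fixed before the data were examined: the largest log2 fold change each way among probes with an adjusted p under 0.05 whose 5 tumor values all lie on one side of all 6 healthy values. Some further probes, chosen after their values were seen, stand among the other observations. Of the 60-mers, 624 were printed under several names (1842 spots, up to 172 for one 60-mer). Identical 60-mers were averaged as 1 probe, which gave 42152 probes, named by the first identifier in sorted order.

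Background was corrected with normexp (offset 50) and log2 ratios were normalized by loess within each array, control spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier spots in either channel (0.108% of all) were left out, saturated spots would have been kept, and no scaling was applied between arrays. Probes well above background in Cy5 on at least 5 of the 11 arrays were tested, which left out 17016. Of the 25136 kept, 1 had too few values for a fit. Tumor minus healthy was fitted with lmFit and eBayes without covariates (prior degrees of freedom 2.25, residual 9), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The values per array (signal, detection, SD, distance to the own group, GC slope) were compared by exact permutation over all splits of 11 arrays into 6 and 5, two-sided, in a family of 8. The distance of an array is the root mean square difference from the mean of the other arrays of its group, 5 for healthy livers and 4 for tumors. Counts of probes seen in one group alone were tested one-sided over the same splits. For a probe not well above background in a whole group only a bound would have been given, and none was needed for the named probes.

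Signal over background sets what can be seen: 17496 probes were well above background on all 11 arrays and 9097 on none. On simulated data with the means and spreads of 24759 real probes (6 against 5 arrays, 200 probes changed), the fit recovered 42% of changes of 1 log2 unit, 74% of 2, 90% of 3 and 94% of 4, with 3 of 153 calls false, and made 0 calls when no probe was changed. The noise was independent between probes, with 1 pooled SD for both groups, whereas real tumors varied more (median SD 0.47 against 0.32 in healthy livers). The data gave 5972 calls, so the adjusted threshold was stricter in the simulation. These shares therefore do not carry over to the real comparison.

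The array barcodes show 3 slides, each scanned in a session of its own. Slide 1 held healthy replicates 1 to 4, slide 2 healthy replicates 5 and 6 with tumor replicates 1 and 2, and slide 3 tumor replicates 3 to 5. Slide was therefore fitted as a fixed block, as a random block (duplicateCorrelation, consensus correlation 0.093) and left out by testing slide 2 alone. Other alternatives were no background correction, plain subtraction, median centring, the processed signals, Aquantile or scale normalization between arrays, the Cy5 channel alone with quantile normalization, the value table, other filters, outlier spots kept, array weights, a replicate block, an intensity trend with robust estimates, each array left out and a stricter threshold of 0.01. A few more were chosen after the data were examined: each probe name kept on its own, a lowess correction of each array's log ratios for GC content, and the removal of probes that ranged over at least 4 log2 units among healthy livers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.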

Results

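Transcript levels were measured in livers of zebrafish (Danio rerio) on 2-colour oligonucleotide arrays, with 6 healthy livers and 5 liver tumors, each on an array of its own. The tumors had been induced with 7,12-dimethylbenz(α)anthracene (DMBA), a polycyclic hydrocarbon carcinogen. Per the labels' protocols, fry were exposed for 24 h to 0.75 ppm at 3 weeks of age and to 1.25 ppm at 5 weeks, fish were sampled 6 to 10 months after the first exposure, and tumors over 3 mm across were diagnosed by histopathology. The labels do not state whether the healthy livers came from carcinogen-treated or vehicle-treated fish. Each liver's RNA carried the dye Cy5 and was hybridised against a Cy3-labelled common reference, so that every value is a log2 ratio of a liver to this reference. The labels describe the reference as a mixture of all 11 RNAs. The livers are separate biological replicates per the labels, and their number limits the precision.

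The median Cy5 signal per array lay between 155 and 397 intensity units, over local backgrounds of 39 to 42 units. Between 20385 and 27463 of the 42152 distinct 60-mers were well above background per array, and no spot was saturated. The 25135 probes tested were those well above background in Cy5 on at least 5 of the 11 arrays. The probes carry an identifier and a 60-base sequence but no gene name in the files used here, so results are given by probe, and no gene, pathway or cell type marker is named.

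The log ratios did not behave as ratios to a reference that holds the 11 RNAs in equal parts. Without dye effects, the ratios to such a mixture average to about 1 over the 11 arrays. The tumor mean then cannot exceed 1.14 on the log2 scale. The mean ratio over the arrays had a median of 1.06 for 18929 probes that did not pass the test between the groups. It had a median of 1.97 for the 1008 probes with all values that were at least 2-fold higher in tumor, 876 of which (86.9%) had a tumor mean above 1.14. It had a median of 0.58 for the 2137 probes at least 2-fold lower. The median of the healthy means was 0.07 for the higher and -0.40 for the lower probes, where an equal mixture would put it at -0.88 and 0.40. On these probes the reference therefore read closer to healthy liver than an equal mixture would. For the lower probes the median of the tumor means was -2.01, so by medians both groups stood below the reference. No dye swap was made, so dye effects of single probes could also enter these values, and the composition of the reference is not settled. In raw ratios a difference between tumor and healthy livers does not depend on it, since the same reference stands in both groups. The loess correction uses the intensities of both channels, so the composition of the reference can enter the normalized values. A deviation from the reference depends on that composition directly.

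The first comparison asked how the profiles of the livers related to each other. The first principal component held 43.5% of the variance and placed all 5 tumors on one side of all 6 healthy livers. The log ratios to the reference, which read closer to healthy liver than to tumor, spread more widely in tumors, with an SD over probes of 1.32 ± 0.302 (SD, n = 5) against 0.610 ± 0.0196 (SD, n = 6) in healthy livers (exact permutation p = 0.002165, the smallest that the splits of 11 arrays into 6 and 5 can give, Benjamini-Hochberg adjusted p = 0.00433 over 8 measures, two-sided). Tumors also lay farther from the mean of the other livers of their own group, by a root mean square of 0.871 ± 0.254 log2 units (SD, n = 5) against 0.617 ± 0.0247 in healthy livers (SD, n = 6; exact permutation p = 0.002165, adjusted p = 0.00433). Scaling all arrays to the same spread of log ratios makes the SDs alike by construction (difference -0.0571, exact permutation p = 0.8788). Quantile normalization of the Cy5 channel alone does so for the SDs of log intensities (difference -0.0116, exact permutation p = 0.4329). Neither therefore tests the difference in spread. The difference in distance of 0.25 was 0.12 without tumor replicate 5 and turned to -0.39 after the scaling of log ratios. On the single slide that held both groups, the SDs were 0.577 and 0.634 in healthy replicates 5 and 6, and 0.956 and 1.25 in tumor replicates 1 and 2.

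**Figure D1:**
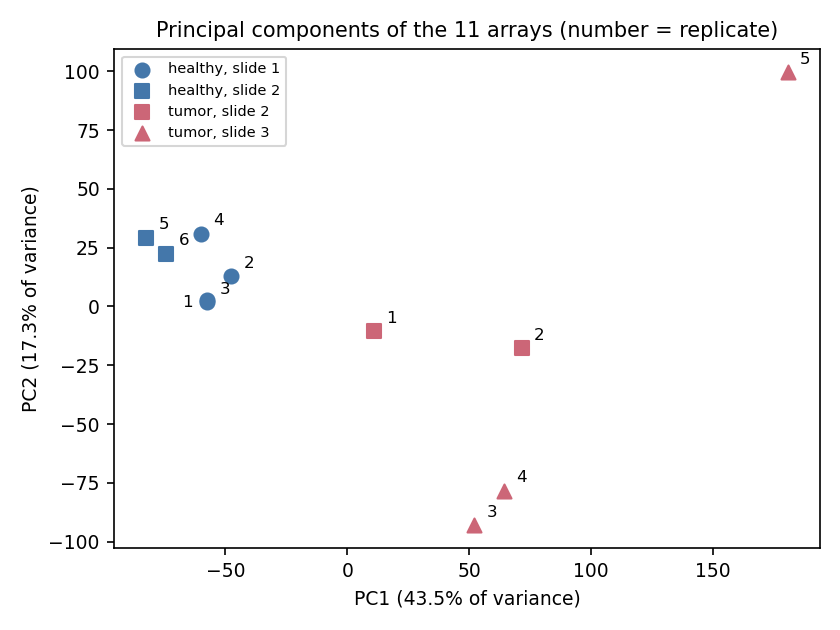
First and second principal components of the log2 ratios of the 11 arrays, one point per liver, with colour for the group, marker shape for the slide and the replicate number beside each point. The 5 tumors lie to the right of the 6 healthy livers on the first component (43.5% of variance), with tumor replicate 1 nearest to the healthy livers.

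Correlations of log ratios between arrays carry the shared reference and the single dye orientation, and so give no level expected without shared expression. Across probes, which are not independent replicates, the 10 pairs of tumors correlated with a median r of 0.69 (range 0.54 to 0.85). The 15 pairs of healthy livers had a median r of 0.04, with a range of -0.29 to 0.70, the lowest being healthy replicates 2 and 5. That median pools unlike sets. Healthy replicates 1 to 3, on slide 1, correlated at 0.46 to 0.55, and replicates 5 and 6, on slide 2, at 0.70. All pairs between these sets were negative (-0.29 to -0.04). Replicate 4, on slide 1, correlated at 0.37 and 0.42 with replicates 5 and 6, and at 0.04 to 0.10 with replicates 1 to 3. The 30 pairs of a tumor and a healthy liver had a median r of 0.37 (range 0.11 to 0.54).

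The second comparison asked which transcripts differed between liver tumor and healthy liver. At an adjusted p under 0.05 (limma, Benjamini-Hochberg), 5972 of the 25135 probes (23.8%) differed, 3475 of them lower and 2497 higher in tumor. The lower probes had a median log2 fold change of -1.21 (quartiles -1.87 and -0.85, median SE 0.27), and the higher probes one of 0.89 (quartiles 0.66 and 1.26, median SE 0.21). Changes of at least 2-fold numbered 2250 lower and 1013 higher. Falls reached further than rises, with 70 probes lower by at least 4 log2 units and 5 higher by as much. Among probes with a value on every array, the tumors all lay above all healthy livers for 1563 and all below for 1870, together 13.9% of 24759 probes, where chance gives 0.433%.

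The balance of lower over higher calls (58.2% lower) differed between ways of processing. It became 24.4% lower (3478 higher, 1124 lower) with median centring in place of loess, which moved the median log2 fold change of all probes from -0.03 to 0.28, and 46.9% lower (1890 higher, 1667 lower) with the Cy5 channel alone. Among changes of at least 2-fold, median centring gave 2558 higher and 972 lower. It was 48.4% lower with the scanner software's processed signals, 48.3% with the authors' value table, 49.4% after a correction for GC content and 40.6% after scaling between arrays. That scaling left 32 calls (19 higher, 13 lower). With the slide as a fixed block, 1027 probes differed (291 higher, 736 lower), and 1247 differed (454 higher, 793 lower) on the slide with both groups alone, where 2 tumors met 2 healthy livers. With the slide as a random block the count was 4713.

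**Figure D2:**
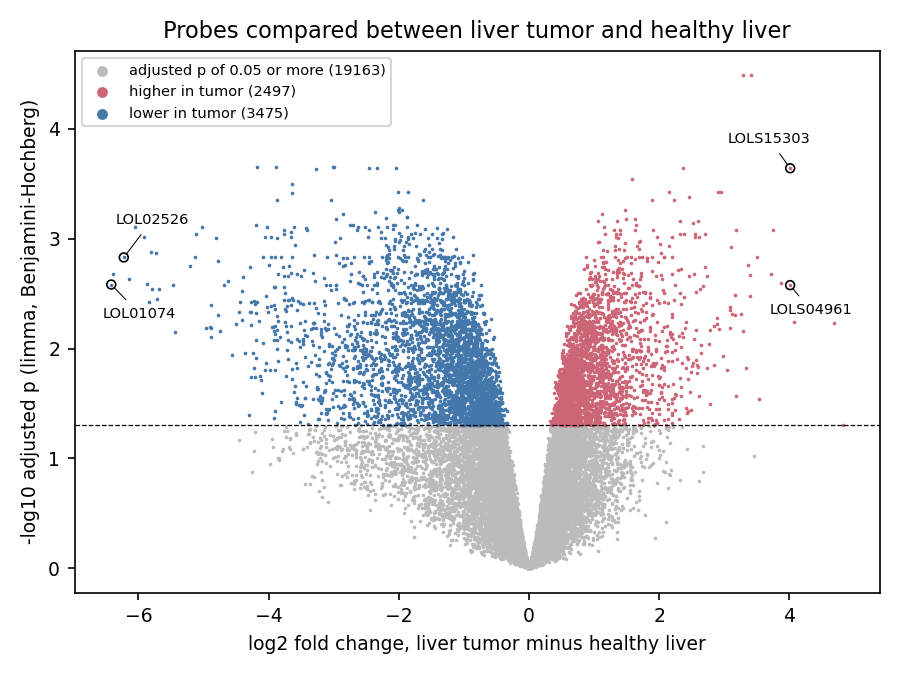
Log2 fold change (tumor minus healthy) against -log10 adjusted p (limma) for each of the 25135 probes tested, with the named probes circled. The 3475 lower probes extend to a log2 fold change of -6.42 and the 2497 higher ones to 4.83, and the dashed line marks an adjusted p of 0.05.

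Among probes with a value on every array whose 5 tumor values all lay above all 6 healthy values, LOLS15303 and LOLS04961 rose the most. LOLS15303 (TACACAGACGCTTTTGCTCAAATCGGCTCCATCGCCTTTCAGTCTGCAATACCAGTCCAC) stood at 0.10 ± 0.61 in healthy livers (SD, n = 6) and 4.11 ± 0.60 in tumors (SD, n = 5), a log2 fold change of 4.01 (SE 0.34, limma adjusted p = 0.0002278) or 16.1-fold. Its tumor values ran from 3.28 to 4.74 and its healthy values from -0.51 to 1.05. LOLS04961 (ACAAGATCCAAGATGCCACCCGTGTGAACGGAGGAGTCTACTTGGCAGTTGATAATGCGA) stood at 0.02 ± 0.89 in healthy livers (SD, n = 6) and 4.03 ± 1.41 in tumors (SD, n = 5), a log2 fold change of 4.01 (SE 0.63, limma adjusted p = 0.002644). With the slide as a block the changes were 3.94 (limma adjusted p = 0.002999) for LOLS15303 and 4.30 (adjusted p = 0.04206) for LOLS04961. The slide with both groups alone gives the same estimates by construction, since no other slide holds both groups. Its limma adjusted p were 0.01326 and 0.04585. After scaling between arrays LOLS15303 rose by 2.59 (limma adjusted p = 0.02665), and LOLS04961 rose by 2.72 without passing the threshold (limma adjusted p = 0.1028, range over its alternatives 0.001308 to 0.1028).

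LOL01074 and LOL02526 fell the most among probes with a value on every array whose tumor values all lay below all healthy values. LOL01074 (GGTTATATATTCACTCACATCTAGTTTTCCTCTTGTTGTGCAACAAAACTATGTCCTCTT), the same 60-mer as LOL02532 and LOL04922, stood at -0.30 ± 1.02 in healthy livers (SD, n = 6) and -6.72 ± 2.53 in tumors (SD, n = 5). Its log2 fold change was -6.42 (SE 1.01, limma adjusted p = 0.002611). LOL02526 (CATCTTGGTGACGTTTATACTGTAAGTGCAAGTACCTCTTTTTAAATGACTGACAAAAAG) stood at -0.89 ± 1.32 in healthy livers (SD, n = 6) and -7.12 ± 1.75 in tumors (SD, n = 5), a log2 fold change of -6.22 (SE 0.83, limma adjusted p = 0.001479). Tumor replicates 2 to 5 read between -8.11 and -7.64 for LOL01074 and between -8.25 and -7.68 for LOL02526, whereas tumor replicate 1 read -2.20 and -4.01. Without that tumor the log2 fold changes were -7.54 and -7.00. All 4 named probes were well above background in Cy5 on all 11 arrays. Probes overlapping these sequences by at least 30 bases, 2 for LOL01074 and 1 for LOL02526, fell alike, with log2 fold changes between -6.40 and -6.06. The one overlapping LOL02526 fell further than it (-6.40) but did not meet the condition of that ranking.

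**Figure D3:**
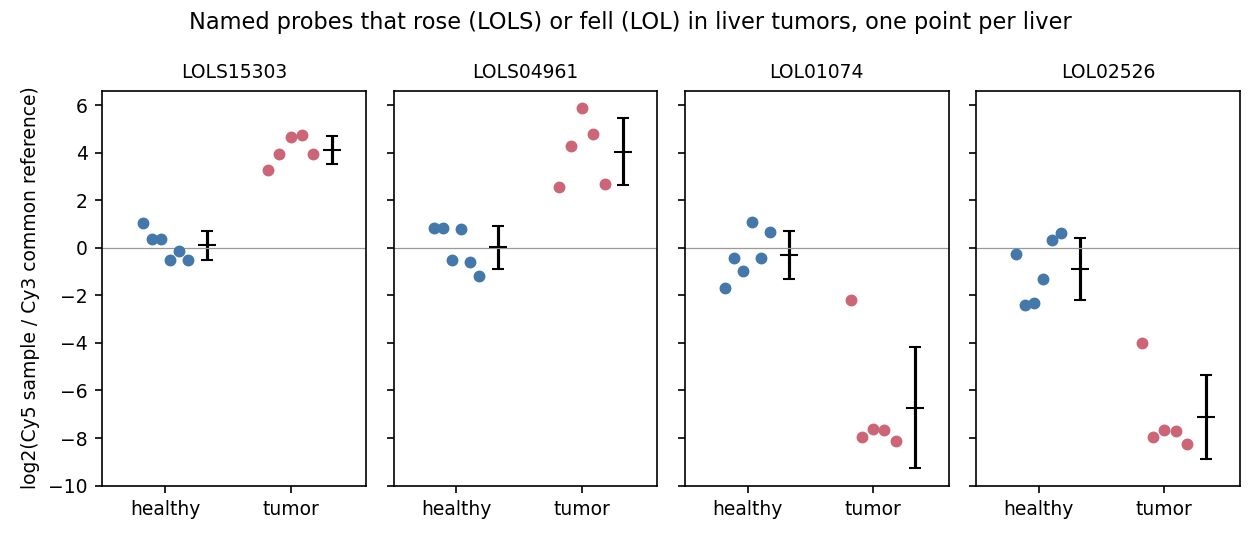
Log2 ratio of each liver to the common reference for the 4 named probes, one point per liver, with the mean and SD of 6 healthy livers and 5 tumors drawn beside the points. The groups do not overlap for any of the 4 probes, and tumor replicate 1 lies above the other 4 tumors for LOL01074 (-2.20) and LOL02526 (-4.01).

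With the slide as a fixed block LOL01074 changed by -5.20 (limma adjusted p = 0.0949) and LOL02526 by -6.44 (adjusted p = 0.01625). The slide with both groups alone, with 2 arrays against 2, gives the same estimates by construction and is no second check. There the 2 probes did not pass the threshold (limma adjusted p = 0.1847 and 0.07436). After scaling between arrays they did not pass it either, at -3.80 and -3.40 (adjusted p = 0.08302 and 0.1356). Over all alternatives the adjusted p ran from 6.379e-05 to 0.1847 for LOL01074 and from 0.0002025 to 0.1356 for LOL02526.

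The 5 tumors shared the calls to different degrees. Over 5830 called probes with a value on every array, tumor replicates 2 to 5 lay beyond all 6 healthy livers, on the called side, for 90.8% to 93.1%, and tumor replicate 1 for 74.0%. These probes were chosen with all 5 tumors in the fit, so a high share is built in. The median size of the change was 0.67 in tumor replicate 1 and 1.00 to 1.25 in the others. Well above background in all 5 tumors and in no healthy liver were 61 probes, a count that 2 of all splits into 6 and 5 reached (exact permutation p = 0.004329, one-sided), the highest other split giving 76. Well above background in all 6 healthy livers and in no tumor were 3 probes (exact permutation p = 0.171, one-sided). Signal differed in the same direction, with a mean of the median Cy5 signals of 280 in tumors and 206 in healthy livers (exact permutation p = 0.07792). Tumors also had more probes well above background, 25652 against 23462 on average (exact permutation p = 0.119). The detection counts were not corrected for this.

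Probes that fell were poorer in G and C than those that rose. The median GC content was 40% for lower, 46.7% for higher and 45% for other probes. Of the 387 probes with under 35% GC, 46.0% were lower and 1.03% higher, and of the 2024 probes with 55% or more, 3.11% were lower and 15.3% higher. The slope of the log2 fold change on GC content was 0.37 per 10 percentage points over all probes, 0.38 within the 11374 probes named A_15_P and 0.31 within the 11376 named LOLS. Slopes of single arrays were 0.607 ± 0.167 in tumors (SD, n = 5) and 0.240 ± 0.0698 in healthy livers (SD, n = 6; exact permutation p = 0.002165, adjusted p = 0.00433). They also differed by slide, from 0.187 to 0.269 on slide 1, 0.245 to 0.531 on slide 2 and 0.555 to 0.831 on slide 3. The group difference in slope of 0.37 was 0.22 without the filter on dim probes (exact permutation p = 0.002165), 0.25 with the Cy5 channel alone (exact permutation p = 0.02165) and 0.032 after scaling between arrays (exact permutation p = 0.6753).

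**Figure D4:**
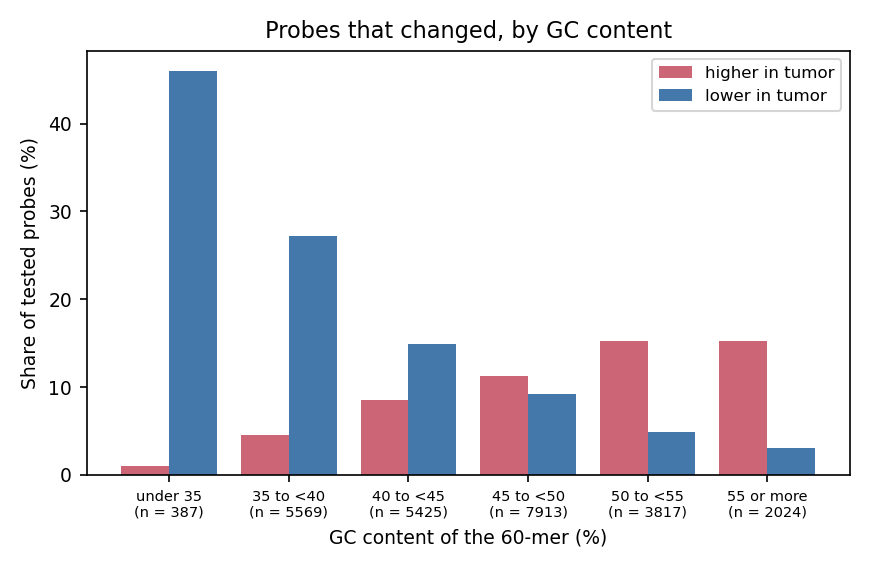
Percent of the tested probes that were higher or lower in tumor, by GC content of the 60-mer, with the number of probes in each bin under the axis. The share of lower probes is 46.0% under 35% GC and 3.11% at 55% or more.

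Among 1395 sets of probes sharing at least 30 bases on the same strand, the first 2 probes of each set had log2 fold changes that correlated at r = 0.94 across sets, with a median absolute difference of 0.13. The first probe was called in 364 sets, and in 287 of these the second was called too, in the same direction in all 287. Spots of one 60-mer on one array differed by a median SD of 0.0896 over 354 such 60-mers, which leaves out differences in amplification, labelling and hybridization between arrays.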

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

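Of the tests below, the comparison of the dye channels and the slide tests of the GC trend and of the wide-ranging probes were chosen after the results were seen. In 26 sets of per-array values, a gap that chance gives in about 1 of 20 sets was found 4 times, in tumor replicates 1 and 5. Those of tumor replicate 1 were for LOL01074, LOL02526 and the share of called probes. The sets are not independent, so the number of gaps does not measure an excess over chance.

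Tumor replicate 5 stood farther from the other tumors, at a root mean square distance of 1.31 log2 units, than the next tumor at 0.828. Tumor replicate 1 stood apart from the other 4 tumors at -2.20 for LOL01074, where the nearest tumor read -7.64. It stood apart at -4.01 for LOL02526, where the nearest read -7.68. It also lay beyond all healthy livers for 74.0% of the called probes, against at least 90.8% in each other tumor. On probes called without it, tumor replicate 1 was nearer to the other tumors than to the healthy livers for 47.1%, whereas the other tumors were so for 77.4% to 83.4%. Without tumor replicate 1 the number of probes called was 6749, and without tumor replicate 5 it was 5669.

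The difference between the groups was larger than the other groupings tried gave. Of 100 splits into 6 and 5, 1 (the real one) called as many as 5972 probes, and the highest other split called 12. Not all splits were tried, so this argues against an arbitrary grouping of the arrays but does not exclude chance. The real split also parts slide 1 (healthy livers only) from slide 3 (tumors only), so it stands out for group and slide together. Of 4095 probes called from slides 1 and 3 alone, 87.5% changed in the same direction on slide 2. The other splits of its 4 arrays gave 77.4% and 66.9%, each counted in the direction with the larger share. This cannot exclude slide as the whole cause, because only 3 splits of 2 arrays against 2 exist and no exact p under 0.333 is possible. The median changes on slide 2 were 0.57 for higher and -0.74 for lower probes. The changes on slides 1 and 3 (1.16 and -1.62) come from the arrays that chose the probes, so a smaller size on slide 2 is built in and says nothing on slide. The Cy3 channel, which holds the same RNA on every array per the labels, called 12 probes (8 higher, 4 lower, limma), with 2218 at an unadjusted p under 0.05. The 12 calls are 0.337% of the 3557 called in Cy5, so an array effect common to both dyes does not account for the calls. Slide effects confined to Cy5, tumor biology and effects of the Cy5 labelling of single RNAs stay open.

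The change between the groups followed probe GC content. A hybridization or scanning bias of the same sign in both dyes is argued against by the Cy3 channel. Its slope of the group difference on GC was -0.274 of that in Cy5, of opposite sign. Yet Cy3 holds the same RNA on every array per the labels, and its group difference still followed GC. Across probes, r was -0.25 in Cy3 and 0.19 in Cy5. A technical GC difference between the groups' arrays is therefore not excluded. The slope was 0.25 per 10 percentage points in Cy5 alone and 0.37 in the ratio, into which Cy3 enters. The class of probe is argued against by slopes within the 2 largest name classes of at least 0.854 of the pooled slope. Differences in amplification or RNA quality that vary from liver to liver without regard to group are argued against by the slopes of single arrays, which did not overlap between the groups (exact permutation p = 0.002165), but a bias shared by the tumors is not excluded. Slide cannot be told apart, because the slopes on slide 2 were separated (0.404 and 0.531 in tumors, 0.245 and 0.364 in healthy livers) by only 0.445 of the difference over all arrays, and 2 arrays against 2 cannot give an exact p under 0.333. A real difference in the transcripts expressed also remains open as an untested explanation, and after the GC correction 5372 probes were called, 4441 of them shared in direction with the 5972.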

How the results depend on the processing

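All alternatives but the probe names on their own, the GC correction and the removal of wide-ranging probes were chosen before the data were examined. Aquantile normalization leaves log ratios as they are and the value table gives nearly the same as the processed signals (5019 and 5010 probes), so neither is counted here. The count of 5972 probes stayed within 1.5 times in 24 of 30 other alternatives, and that of 3263 probes changed at least 2-fold in 25 of 29. Of these alternatives, 11 each leave out 1 array and so largely repeat each other. A like count does not mean like calls. Median centring counted as within, with 4602 probes, but had 3478 higher and 1124 lower and shared 58.7% of the 5972 calls. Leaving out each array in turn gave 4315 to 6749 and 2669 to 3949 probes. Scaling between arrays gave 32 and 31 probes and, by making the spreads of all arrays alike, turned the SD difference to -0.0571 and the difference in distance to the own group to -0.39 (from 0.25). An unadjusted p under 0.05 was then reached by 3460 probes. The Cy5 channel alone gave 3557 probes and an SD difference of -0.0116 in log intensities, since quantile normalization fixes that spread. The slide as a fixed block gave 1027 and 1001 probes, and slide 2 alone 1247 and 1247. In both, the contrast rests on the same 4 arrays, so these 2 alternatives largely repeat each other although both are counted. Of the 5972 calls, which include those arrays in their fit, 583 and 598 were shared there. The replicate block gave 2014 and 1769 probes. Replicate numbers did not pair the livers (correlations of deviations of same-numbered livers from -0.21 to 0.09, and 0 of 5 tumors correlated best with their own number). The threshold of 0.01 gave 2035 probes. LOLS15303 stayed called with the same direction in 29 of 29 alternatives, LOLS04961 in 28, LOL02526 in 27 and LOL01074 in 26, the others keeping the direction. These probes were chosen for large called changes on the same arrays, so high counts and a kept direction are largely built in. Where not explained by construction, the cause was not tested. Gene list tests (camera with an estimated correlation, fry) and the mean of a gene's probes were not run, for want of gene names. Signal near background limits the 17016 probes left out: without the filter 5929 were called, and 4548 among those well above background on all 11 arrays.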

Other observations

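The test of the slide on wide-ranging probes was chosen after the result was seen, and the 2 probes in this part were chosen after their values were seen. The healthy livers differed sharply from each other on a set of bright probes. On 472 probes the log2 ratio ranged over at least 4 units among the 6 healthy livers. Their mean log2 intensity over both channels had a median of 10.6, against 8.96 for all tested probes. The median log2 ratio of this set was -2.58, -2.35, -2.45, -1.50, 0.67 and 0.52 in healthy replicates 1 to 6, and -2.95, -3.76, -3.19, -3.84 and -4.56 in tumor replicates 1 to 5. Of these probes 64 were called lower and 3 higher in tumor, where 23.8% of all tested probes were called. A wide range among healthy livers raises the SE, so few calls are built in.

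The widest range, 9.47, belonged to LOLS00983 (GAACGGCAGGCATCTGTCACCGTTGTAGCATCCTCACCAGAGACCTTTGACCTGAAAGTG). It read -6.03, -6.41 and -6.10 in healthy replicates 1 to 3 and 1.73, 2.01 and 3.06 in replicates 4 to 6. In tumor replicates 1 to 5 it read -6.60, -7.28, -3.40, -6.65 and -7.12. Its log2 fold change of -4.25 (SE 1.97) did not pass the threshold (limma adjusted p = 0.1342). The next widest, LOLS15767 (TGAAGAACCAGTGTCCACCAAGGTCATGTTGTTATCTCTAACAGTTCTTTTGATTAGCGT), did not follow that arrangement. It read 1.32, 0.01, -7.71, -2.35, 0.77 and -1.18 in healthy replicates 1 to 6, and -8.31, -2.50, -1.88, -1.45 and -8.90 in tumor replicates 1 to 5 (limma adjusted p = 0.2495).

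A tumor labelled as healthy in 1 array alone is argued against on the called probes. For this, each of the 6 healthy arrays was left out of the fit in turn. On the probes then called, it lay nearer to the other healthy livers than to the tumors for at least 83.8%. With 1 array left out at a time, tumor tissue shared by several healthy livers, such as replicates 1 to 3, could not be seen. Few of the 472 probes were called (64 lower and 3 higher in the full fit), so the source of their differences is not settled. Slide cannot be told apart for the set as a whole, because healthy replicate 4, scanned with replicates 1 to 3, lay nearer to replicates 5 and 6 of the other slide on 49.2% of the probes. The labels give no sex, age or feeding state of single fish, and no biological explanation was tested. Without these 472 probes, 6029 probes were called.

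One 60-mer (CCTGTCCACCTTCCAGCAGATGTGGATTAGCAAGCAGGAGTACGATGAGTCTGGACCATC) was printed under 172 names and gave a median SD of 0.119 between its spots on one array. Its log2 ratio was 0.122 ± 0.321 in healthy livers (SD, n = 6) and 1.27 ± 1.12 in tumors (SD, n = 5), with single tumors from 0.107 to 2.96 (exact permutation p = 0.02165, adjusted p = 0.03464 over 8 measures). In the fit over all probes its log2 fold change of 1.15 (SE 0.43) did not pass the threshold (limma adjusted p = 0.07609).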
